A study of Mus musculus with 35 samples.

How the data were processed

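RNA was sequenced from primary microglia that had been sorted from mouse cerebellum or forebrain, with an ultra-low-input library protocol. The 35 libraries fall into 12 groups. Mice with a Csf1 deletion driven by Nestin-Cre (NesCre Csf1fl/fl) were compared with Csf1fl/fl controls at postnatal day 8 (P8) and at 9 weeks, and mice homozygous for a LacZ insertion in Il34 were compared with wild-type controls at 9 weeks. Each comparison was made in cerebellum and in forebrain. The series' design text calls the samples of a group biological replicates. Group and replicate were taken from the sample titles. One P8 forebrain control carried no replicate number, and the 9-week NesCre cerebellum libraries are numbered 1, 3 and 4.

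Per the submitters' processing notes, reads were aligned with STAR 2.5.3 to mouse build mm10 and assigned to genes with featureCounts. The strand setting, the annotation release and the normalization step were not given in the sources used here. The authors deposited 6 tables, 1 per region, age and mutant, and each was treated here as normalized on its own. The sources do not say whether the factors were set per table. The deposited values are a signal per gene: in all 35 columns, 100% of values are whole read counts divided by 1 factor per library, plus a constant of 0.1, within a tolerance of 0.01 reads. The tables hold between 8539 and 9670 genes. In 5 of the 6 deposited tables every gene is above 10 in all libraries of at least 1 group, so genes silent in both groups were not analysed here. In the P8 forebrain table, 8499 genes pass that filter and 1113 do not; all 9612 pass if the unnumbered control library is treated as its own group. No mitochondrially encoded gene is in the tables analysed here. A spreadsheet program had turned 15 to 17 gene names per table into dates, and these were left out of every join by gene name.

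The design fixed before the data were examined assumed read counts and named edgeR as the test, with limma as the test for normalized values. Because the authors' values are normalized, limma-trend on log2(value + 1) within each table is the test of every genotype comparison (limma 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes of the table and a threshold of 0.05. Log2 changes are on that scale and understate the change of low genes. Each fit held only the 2 groups compared, with no covariate. Means and SDs are of the deposited normalized values. Differences between 2 genotype effects are given as the difference of their log2 changes with the combined standard error (SE), as the design prescribed for normalized values; a joint limma test of the same difference was chosen after seeing the data. The comparison of regions within controls was to be run only on counts. It was run with edgeR 4.0.16 on the recovered reads (TMM factors, filterByExpr), also chosen after seeing the data, and stands among the other observations. Levels were not compared across tables outside such a fit.

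Gene lists were fixed in advance: 29 lists, of which 28 can be tested as lists. They hold programs of microglia and macrophages, and markers of other cells that a sort could carry. A list was tested in a comparison where at least 3 members were measured, with limma's camera at a preset correlation of 0.01 and adjustment over the lists tested. Beside it stand camera with a correlation estimated per list and fry. Neither camera with an estimated correlation nor fry's directional test made any call in the 6 genotype comparisons. Fry's test for changes in mixed directions did pass for some lists, for example lipid efflux genes in the Il34 forebrain (adjusted p = 4.11e-05). Each list is described by its median log2 change, by the members past the threshold over all genes, and by those past it adjusted over the list alone. Lists overlap (Apoe, Ctsd and Lpl are each in more than 1). The annotation is GENCODE vM21 on GRCm38, which is the assembly of mm10, and 95.4% to 95.7% of the symbols per table were found in it. Coordinates are those of the gene.

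Named genes follow a rule fixed with the design. Among genes past the threshold, with an average log2 CPM of at least 3 and no overlap between the libraries of the 2 groups, the 10 with the largest change in each direction are eligible, leaving out predicted and ribosomal protein genes. Where none passes, the 3 smallest p in each direction are given as values. From each list come up to 4 called members, or up to 3 of the highest expressed as values, and for differences between effects up to 5 genes in each direction. Csf1, Il34 and Csf1r are given throughout. Other members of a list, chosen after their values were seen, are named where they passed the threshold adjusted over the list alone or where a called gene belongs to the same complex.

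Alternatives set with the design were quantile normalization, a stricter filter of 5 CPM, a pseudocount of 0.1, a block on the replicate number, leaving out each library in turn, and for lists the estimated correlation, fry, and members above the expression minimum only. The recovered reads were also tested with edgeR (TMM or RLE factors), with DESeq2 1.42.0, with voom and sample quality weights, and in 1 edgeR fit of all groups. These tests, a per-library GC correction (lowess, span 0.3), camera with a variance trend, list tests under the block and the GC correction or without single libraries, and the common gene filter for the P8 forebrain were chosen after seeing the data. For the genotype comparisons a test with no filter was not run, because limma used every gene of the already filtered tables; for the regions it was run with edgeR. Whether same-numbered libraries deviate together was checked as well. Among 35 pairs of libraries within groups, chi-square per degree of freedom was 2.44 to 6.87, so no pair agreed within sampling noise.

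Depth is low. Reads in the genes of a table ran from 503424 to 1742629 per library, and the median gene held 31 to 65 reads per library depending on the table. The tests were tried on simulated counts with the tables' own means and depths, with 100 genes changed at each fold. Of 2-fold changes, limma recovered 61% in the Csf1 cerebellum at 9 weeks, 73% in the forebrain at 9 weeks, 54% in the cerebellum at P8, 42% in the forebrain at P8, 8% in the Il34 cerebellum and 53% in the Il34 forebrain. Of 4-fold changes it recovered 91%, 97%, 92%, 87%, 62% and 89%, in the same order. False calls among unchanged genes numbered 9, 20, 6, 9, 6 and 5. Genes were simulated independently of each other, with the changed genes of both folds in the same run. Recovery may therefore be lower in these data, where libraries share variation and few genes are called. The library kit does not mark strand, so reads of a gene and an overlapping antisense gene cannot be told apart, and ribosomal protein genes share sequence with many pseudogenes.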

Results

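Microglia are the macrophages of the brain parenchyma, and their receptor CSF1R has 2 ligands, CSF1 and IL-34. The mutants remove 1 ligand each: Nestin-Cre deletes Csf1 in cells of the neural lineage, and the LacZ insertion disrupts Il34 in the whole animal. The comparisons ask how the transcriptome of microglia in cerebellum and forebrain depends on each ligand. At P8, 3 NesCre and 3 control libraries were sequenced per region, with 507917 to 1259164 reads in table genes for cerebellum and 503424 to 1049734 for forebrain. At 9 weeks there were 3 NesCre and 3 control cerebellum libraries (995596 to 1631725 reads), and 4 NesCre and 3 control forebrain libraries (1385403 to 1742629 reads). The Il34 groups held 2 LacZ and 2 control cerebellum libraries (508182 to 901522 reads) and 3 LacZ and 3 control forebrain libraries (551909 to 873167 reads). The shallowest libraries were NesCre replicate 1 of the P8 forebrain, NesCre replicate 3 of the P8 cerebellum and both LacZ cerebellum libraries (539339 and 508182 reads).

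The deleted genes cannot check the labels here, because both ligands come mainly from other cells than the sorted ones. Csf1 transcripts were read in microglia of every group. Mutant and control means in normalised read counts were 39.8 ± 17.5 and 53.5 ± 15.3 in the P8 cerebellum, 27.3 ± 14.5 and 32.1 ± 8.59 in the P8 forebrain, 34.7 ± 6.11 and 37.4 ± 11.5 in the 9-week cerebellum, and 42.0 ± 2.55 and 33.4 ± 8.83 in the 9-week forebrain (SD; adjusted p = 0.687, 0.997, 0.997 and 0.988). In the Il34 mutants, Csf1 was at 22.7 ± 4.26 against 10.2 ± 3.87 in forebrain (log2 change 1.14 ± 0.39 SE, adjusted p = 0.373) and at 21.4 ± 0.0155 against 11.9 ± 1.02 in cerebellum (adjusted p = 0.997). Il34 was measured only in the 9-week Csf1 cerebellum table, at 10.1 ± 0.206 in mutants and 12.2 ± 1.24 in controls. Csf1r was abundant and did not pass the test in any comparison, with log2 changes from -0.10 in the Il34 forebrain to -0.02 in the Il34 cerebellum. The Y-linked Ddx3y was read in every library, from 61.2 to 177.4 normalised counts.

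In the cerebellum at P8, 4 genes were lower in the Csf1 mutants than in controls. Spp1, which encodes the secreted phosphoprotein osteopontin (chromosome 5, 104435118 to 104441050), fell from 1370 ± 415.7 in controls to 224.1 ± 145.8 in mutants (SD, n = 3 each), a log2 change of -2.88 ± 0.41 SE with an adjusted p of 0.00461. Jam2, a junctional adhesion molecule (chromosome 16, 84774123 to 84825928), fell from 72.7 ± 1.36 to 21.2 ± 5.49 (log2 change -1.76 ± 0.26, adjusted p = 0.00461). The tetraspanin Cd9 (chromosome 6, 125460266 to 125494791) fell from 993 ± 187 to 511 ± 70.3 (-0.95 ± 0.15, adjusted p = 0.00746). The lysosomal protease Ctsd (chromosome 7, 142375911 to 142388038) fell from 11330 ± 523.7 to 7394 ± 1120 (-0.63 ± 0.12, adjusted p = 0.0334). For each of these genes all 3 mutant libraries lay below all 3 controls. The naming rule asks for this of genes chosen by size of change, and 650 of all 8539 genes lay wholly below.

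The other 30 called genes were higher in the mutants. Rnf187, a RING-type ubiquitin ligase (chromosome 11, 58932288 to 58938916), rose from 16.9 ± 1.35 to 121 ± 61.1 (log2 change 2.61 ± 0.34, adjusted p = 0.00461). Among the others, Snx20, a sorting nexin, changed by 2.91, the transcription factor Foxo3 by 2.84, the immediate early gene Ier2 by 1.89 and the membrane protein gene Clptm1 by 1.64. Several are familiar microglial genes. Lamp1, a membrane glycoprotein of lysosomes, rose from 433 ± 139 to 1134 ± 235 (1.42 ± 0.21, adjusted p = 0.00461). C1qc, 1 of the 3 chains of complement C1q, rose from 752 ± 73.2 to 2109 ± 857 (1.39 ± 0.23, adjusted p = 0.0125), while C1qa and C1qb, chosen after their values were seen, had log2 changes of 0.02 and -0.00. Spi1, which encodes the myeloid transcription factor PU.1, rose from 72.6 ± 5.28 to 202 ± 80.6 (1.38 ± 0.25, adjusted p = 0.0207). Bin1, a membrane-curvature protein on the homeostatic list, rose by 0.92 on the log2 scale, and the ribosomal protein gene Rps2 by 1.35. In a test chosen after the result was seen, these genes (29 or 30 measured per table) also vary together between libraries of the same genotype: their mean pairwise correlation within groups was 0.605, 0.54, 0.444 and 0.641 in 4 of the 5 other tables, above the 99th percentile of random sets, and 0.233 in the Il34 cerebellum, which was not.

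In total 34 of 8539 genes passed in limma, 30 higher and 4 lower, with 837 genes at an unadjusted p under 0.05. Tests on the recovered reads called 52 genes in edgeR (41 higher, 11 lower), 69 in DESeq2 (50 higher, 19 lower) and 69 in voom with quality weights (49 higher, 20 lower), and each of these included all 34. In 1 edgeR fit of all groups, over the 7531 genes present in every table, it was 51 (37 higher, 14 lower) and shared 27 of the 34; Spp1 and Foxo3 were not among the genes tested there, and Lamp1 and Snx20 did not pass (adjusted p = 0.219 for both). The count was 6 without NesCre replicate 2, 12 without NesCre replicate 3, 12 without control 1, 7 without control 2 and 60 without control 3. Spp1, Rnf187 and Rps2 kept their call without any single library. Jam2 missed the threshold without control 2 (adjusted p = 0.0537), Lamp1 and Ier2 without NesCre 2 (both 0.0521), and Clptm1 without NesCre 2 (0.0755) or control 2 (0.0511). Cd9 lost its call without NesCre 2 (0.0911), control 1 (0.0617) or control 2 (0.0875), and Ctsd without NesCre 2 (0.184), NesCre 3 (0.0539), control 1 (0.179) or control 2 (0.156), and also under quantile normalization, where its log2 change was -0.32 (0.168). Without NesCre 2, NesCre 3, control 1 or control 2, the adjusted p was 0.0945, 0.0536, 0.0617 and 0.0744 for C1qc and 0.139, 0.0798, 0.0578 and 0.13 for Spi1. Snx20 lost its call without any library but control 3 (adjusted p = 0.0547 to 0.0945). Foxo3 and Bin1 lost theirs without NesCre 1 (0.0851 and 0.0792), NesCre 2 (0.0945 and 0.139), NesCre 3 (0.102 and 0.0683) or control 2 (both 0.13), and Foxo3 also at the pseudocount of 0.1 (0.0714).

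Of the gene lists called in the P8 cerebellum, the disease-associated microglia list had the smallest adjusted p from camera at the preset correlation. Its genes are the activation program that includes Spp1, Cd9 and Ctsd: 22 of 28 members had a negative log2 change, with a median of -0.47 (camera adjusted p = 5.44e-07; adjusted p = 0.698 with an estimated correlation). Over all genes 3 members fell and none rose; adjusted over the list alone, 16 fell and 1 rose. The 16 include the phagocytic receptor Clec7a (log2 change -1.15), the integrin Itgax (-1.47), the growth factor Igf1 (-0.75), lipoprotein lipase Lpl (-0.75) and the cystatin Cst7 (-1.28), and the 1 higher member is the receptor kinase Axl (0.83); none of these passed over all genes. The lipid efflux list fell too, with a median of -0.29 over 15 genes (adjusted p = 0.0212; 0.698 with an estimated correlation). None of its members passed over all genes and 6 fell adjusted over the list alone, among them the apolipoprotein Apoe (9345 ± 296 against 12710 ± 821.3, log2 change -0.44) and the cholesterol transporter Abcg1 (-0.66). Glycolysis and hypoxia genes had a median of -0.33 with 14 of 18 negative (adjusted p = 0.00271; 0.698 with an estimated correlation), 0 called over all genes by limma and 4 lower adjusted over the list alone: Bnip3, the glucose transporter Slc2a1, Hif1a and lactate dehydrogenase Ldha (-0.46).

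The homeostatic list had a median of -0.17, with 24 of 29 members negative (adjusted p = 0.0481; 0.698 with an estimated correlation). Its 1 called member over all genes, Bin1, rose; adjusted over the list alone Bin1 rose, and the purine receptor P2ry12 (-0.58) and Gpr34 (-0.45) fell. Interferon-stimulated genes were shifted up (median 0.19, 14 of 20 positive, adjusted p = 0.00824), as were antigen presentation genes (0.20, 13 of 17, adjusted p = 0.0310) and markers of border-associated macrophages, which line the brain's surfaces and vessels (0.26, 14 of 14, adjusted p = 0.0150). No member of these 3 lists passed limma's threshold over all genes or adjusted over the list alone, and each adjusted p was 0.698 with an estimated correlation. The border macrophage markers include the mannose receptor Mrc1 (0.24) and F13a1 (0.51), which moved beside the interferon and antigen presentation genes. Lysosome genes were not called as a list (adjusted p = 0.458), with Lamp1 higher and Ctsd lower over all genes, and 4 higher and 3 lower adjusted over the list alone. The endothelial marker Cldn5 was at 7.20 ± 5.60 in mutants and 118.1 ± 120.2 in controls (log2 change -3.29, adjusted p = 0.0797). For the lists of transforming growth factor beta signalling and of p53, neither called, the signs differed: medians of -0.02 and -0.07, means of 0.05 and 0.03, and tests pointing up and down.

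Single libraries decided several of these list calls. The disease-associated and glycolysis calls stood without any library. The homeostatic call was lost without NesCre 1 (adjusted p = 0.13), NesCre 2 (0.369), control 2 (0.299) or control 3 (0.0627), the interferon call without NesCre 2 (0.0555), and the antigen presentation call without NesCre 1 (0.126), NesCre 2 (0.131) or control 2 (0.377) and after GC correction (0.0587). The lipid efflux call was lost without NesCre 2 (0.0555), control 1 (0.133) or control 2 (0.0817), and that of border macrophages without NesCre 2 (0.381) or control 3 (0.405).

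**Figure D1:**
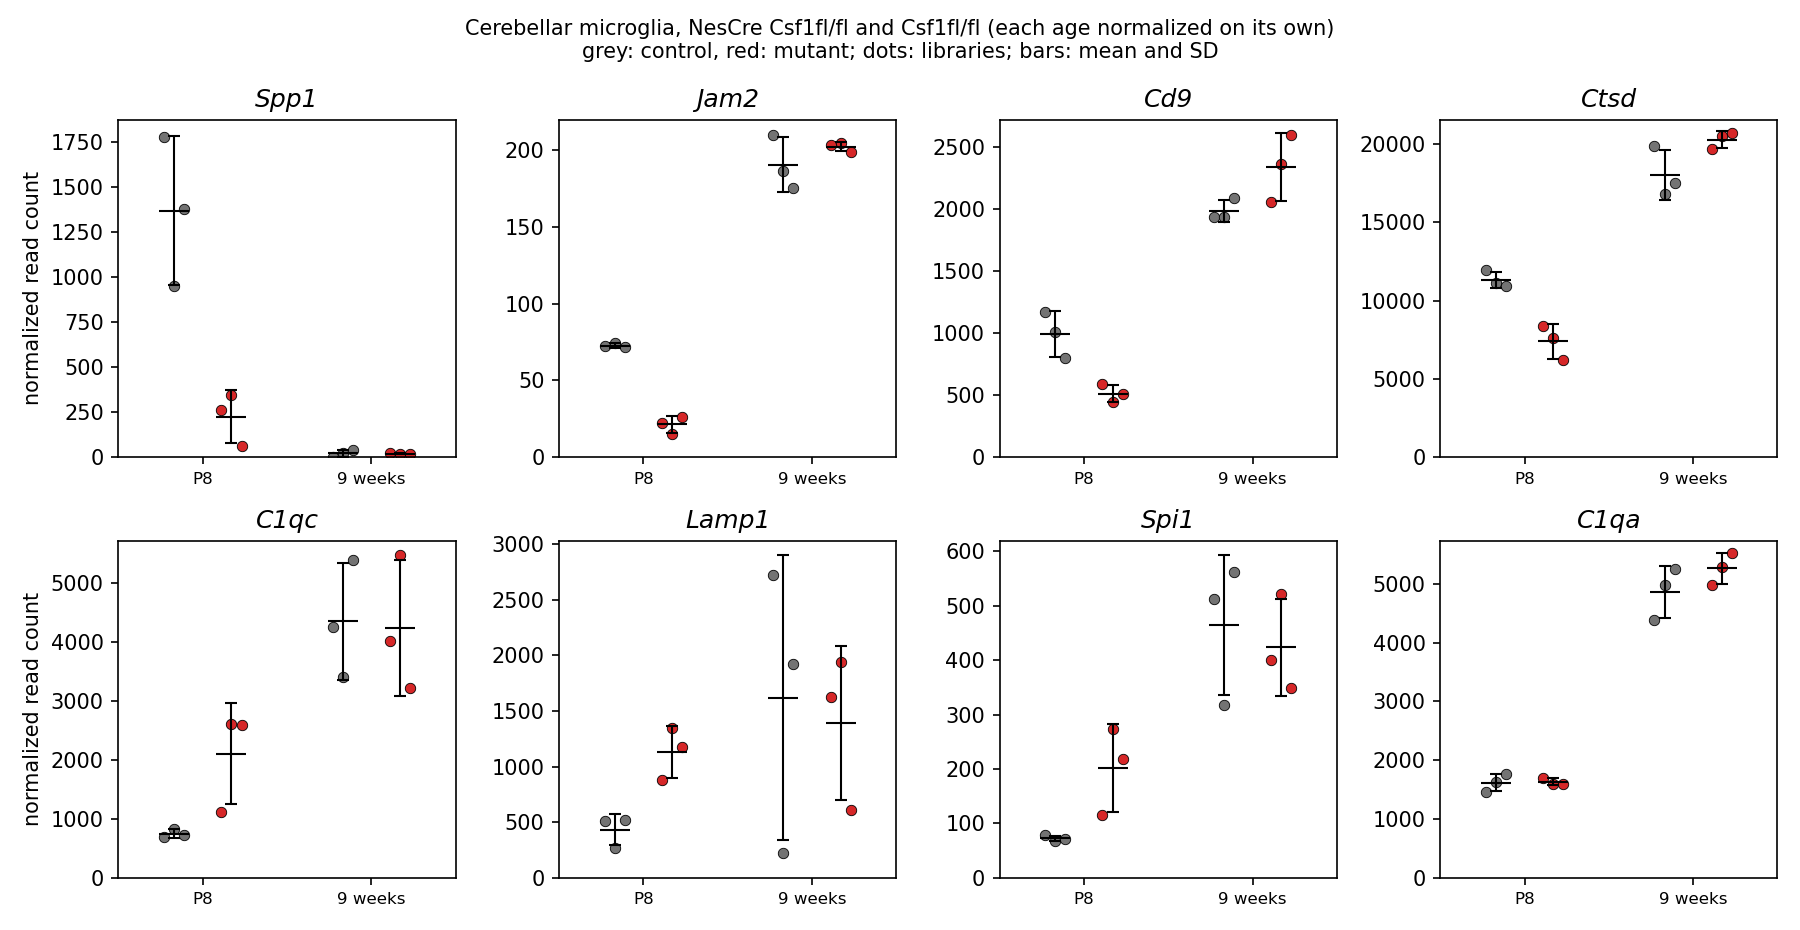
Normalised read counts (deposited values, vertical axis, 1 panel per gene) of 8 genes in cerebellar microglia of controls (grey) and NesCre Csf1fl/fl mutants (red) at P8 and at 9 weeks; dots are libraries and bars are mean ± SD of 3 libraries. At P8 the mutant libraries lie below the controls for Spp1, Jam2, Cd9 and Ctsd and above them for C1qc, Lamp1 and Spi1, while C1qa does not separate.

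In the forebrain at P8 no gene passed. Of 9612 genes, limma called 0, with 421 at an unadjusted p under 0.05 and a smallest adjusted p of 0.997; edgeR, DESeq2 and voom also called 0, and the same filter as in the other tables left the count at 0. Without NesCre replicate 3 limma called 1 gene, and with a block on replicate number, which holds only 2 libraries per group, it called 8. The genes with the smallest p, given as values, were Coq4 of ubiquinone synthesis (18.0 ± 1.09 in mutants, 3.50 ± 4.46 in controls, log2 change 2.53), the helicase Dhx33 (0.90) and the DNA polymerase Polq (1.90) with higher means, and the calponin Cnn3 (-2.10), fibronectin Fn1 (-1.75) and the GTPase Rab34 (-1.60) with lower means. Disease-associated genes did not pass as a list (adjusted p = 0.0812), and Apoe, Ctsd and Ctsb had log2 changes of -0.19, -0.18 and -0.40.

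The only list called in the P8 forebrain holds markers of endothelial cells and pericytes, cells of the vessel wall. Of 9 measured members 8 had a negative change, with a median of -0.88 (camera adjusted p = 0.0170; adjusted p = 0.888 with an estimated correlation), and limma called 0 members over all genes and 0 adjusted over the list alone. The tight junction gene Cldn5 was at 36.4 ± 31.5 in mutants and 88.3 ± 52.0 in controls (-1.97), Pecam1 changed by -0.07 and Rgs5 by -0.02. The call was lost without NesCre 2 (adjusted p = 0.181), NesCre 3 (0.0783) or control 1 (0.0982). Signs of median, mean and test differed for the interferon list (0.02, -0.07, up) and the ribosomal protein list (-0.01, 0.03, up), and the tests of the cholesterol, complement, transforming growth factor beta and oligodendrocyte lists pointed up against a negative median; none of these was called.

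In the cerebellum at 9 weeks the single genes did not pass either, while 5 lists passed, 4 of them with small median shifts and neutrophil markers with a larger one. Limma called 0 of 9670 genes (408 at an unadjusted p under 0.05, smallest adjusted p 0.380), edgeR and voom 0 and DESeq2 1. Without control replicate 2 limma called 3. With a block on replicate number, which keeps only libraries whose number both groups hold (2 per group), it called 35. The genes with the smallest p were carboxypeptidase E, Cpe (25.2 ± 2.43 in mutants, 5.28 ± 1.49 in controls, log2 change 2.08, adjusted p = 0.380), BC025920 (2.49) and the complement receptor C3ar1 (1155 ± 135 against 804 ± 84.6, 0.52) with higher means. Csmd3 (80.5 ± 20.1 against 214 ± 78.0, -1.37, adjusted p = 0.380), the phosphatase Ptprm (-0.89) and Arhgap39 (-0.74) had lower means. At this depth, a 2-fold change was recovered in 61% of simulated genes.

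Lipid efflux genes had positive changes in 14 of 14 members, with a median of 0.29 (camera adjusted p = 0.000736; 0.252 with an estimated correlation). Their values include Apoe, the main apolipoprotein of the brain, at 3808 ± 735 in mutants and 2504 ± 1011 in controls (log2 change 0.66 ± 0.21), and Abcg1 (0.27). The disease-associated list was up in 19 of 27 members with a median of 0.19 (adjusted p = 0.00446; 0.567 with an estimated correlation), with Ctsd at 0.17 and Ctsb at 0.19. Interferon-stimulated genes were down in 23 of 28 (median -0.26, adjusted p = 4.91e-06; 0.252 with an estimated correlation), including Slfn8 (-0.28). Ribosomal protein genes were up in 72 of 74, with a median of 0.23 (adjusted p = 2.44e-11; 0.628 with an estimated correlation). Neutrophil markers, which belong to blood cells, were lower in 6 of 6 members (median -1.56, adjusted p = 0.0308; 0.628 with an estimated correlation), with the calgranulin S100a8 at 90.4 ± 84.6 in mutants and 156 ± 60.1 in controls, S100a9 at a change of -1.73 and Ngp at -1.74. In these 5 lists limma called 0 members over all genes and 0 adjusted over the list alone. The disease-associated call was lost without control 1 (adjusted p = 0.366) and the neutrophil call without NesCre 4 (0.867), control 2 (0.295) or control 3 (0.204). The endothelial list, not called, had a median of -0.08, a mean of 0.09 and a test pointing down.

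In the 9-week forebrain, limma called 0 of 9424 genes (399 at an unadjusted p under 0.05, smallest adjusted p 0.429). EdgeR and voom called 0 and DESeq2 2, and limma called 1 without NesCre 1, control 2 or control 3. With a block on replicate number limma called 12. The smallest p went to Erdr1 (174 ± 42.3 in 4 mutants, 86.0 ± 17.6 in 3 controls, log2 change 0.99, adjusted p = 0.429), the pyrophosphatase Enpp1 (2.07) and Zfp956 (1.26). On the lower side stood clusterin, Clu, an apolipoprotein abundant in astrocytes (6.15 ± 4.24 against 41.6 ± 25.5, -2.46 ± 0.50, adjusted p = 0.429), the kinase Dyrk1b (-1.46) and the leukotriene receptor Cysltr1 (-0.60).

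Small shifts of 4 lists reached the threshold in the 9-week forebrain, each with a camera adjusted p of 0.0491. The disease-associated list was up in 17 of 23 members (median 0.10; Ctsd 0.21, Ctsb 0.17). Interferon-stimulated genes were down in 16 of 23 (median -0.13; Trim30a -0.35), immediate early and heat shock genes in 16 of 22 (median -0.11; Jun -0.17), and endothelial markers in 9 of 10 (median -0.45; Cldn5 -0.60, Pecam1 -0.33). With an estimated correlation the adjusted p was 0.542, 0.501, 0.565 and 0.501. Limma called 0 members over all genes, and adjusted over the list alone 1 immediate early gene, Klf2, fell (-1.27). The disease-associated call ended without NesCre 1 (adjusted p = 0.0823), NesCre 2 (0.168), NesCre 4 (0.143), control 1 (0.434) or control 3 (0.133), and the interferon call without NesCre 2 (0.0765), NesCre 3 (0.117), NesCre 4 (0.104), control 1 (0.0749), control 2 (0.343) or control 3 (0.133). The immediate early call ended without NesCre 1 (0.271), NesCre 2 (0.168), NesCre 4 (0.0981), control 1 (0.215) or control 3 (0.144), and the endothelial call without NesCre 2 (0.168), NesCre 4 (0.139), control 1 (0.215) or control 3 (0.173). GC correction ended the disease-associated (0.067) and interferon (0.0557) calls, and a variance trend the interferon call (0.0555). Signs of median, mean and test differed for 4 lists that were not called: cell cycle (0.03, -0.00, up), complement (0.01, -0.10, down), transforming growth factor beta (median -0.01, test up) and cerebellar neurons (0.19, 0.02, down).

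In forebrain libraries of Il34 mutants 15 genes differed from controls, 10 higher and 5 lower. Apoe (chromosome 7, 19696109 to 19699188) rose from 435 ± 139 in controls to 1015 ± 16.6 in mutants (SD, n = 3 each; log2 change 1.27 ± 0.16, adjusted p = 8.8e-05). Ptchd1, a patched-domain membrane protein gene (chromosome X, 155573455 to 155623814), rose from 41.1 ± 3.65 to 138 ± 22.4 (1.71 ± 0.21, adjusted p = 8.8e-05). The nuclear long non-coding RNA Neat1 rose from 47.9 ± 13.2 to 113 ± 25.3 (1.23 ± 0.23, adjusted p = 0.0165), and C3ar1, the receptor for complement C3a, from 385 ± 38.8 to 606 ± 25.9 (0.66 ± 0.13, adjusted p = 0.0193). The lymphocyte receptor gene Ly9 (1.87) and the motor protein gene Myo5a (1.56) also rose. Upk1b, a uroplakin of the tetraspanin family (chromosome 16, 38773184 to 38800328), fell from 145 ± 18.5 to 54.8 ± 13.5 (-1.41 ± 0.21, adjusted p = 0.000949). The fructose transporter Slc2a5 fell from 639 ± 96.8 to 383 ± 54.4 (-0.74 ± 0.14, adjusted p = 0.0187), the sulfotransferase Gal3st4 from 371.8 ± 29.98 to 225 ± 21.7 (-0.72 ± 0.14, adjusted p = 0.0193), and the adenylyl cyclase Adcy8 (-2.05) and Vapa of the endoplasmic reticulum (-1.16) fell as well.

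A further 4 of the 10 higher genes are known from vessels or choroid plexus. Itm2a, a membrane protein gene of brain endothelium (chromosome X, 107397099 to 107403376), rose from 1.81 ± 0.292 to 39.9 ± 25.3 (3.66 ± 0.46, adjusted p = 8.8e-05), the thyroid hormone transporter Slco1c1 from 1.499 ± 1.414 to 17.5 ± 7.29 (3.00 ± 0.50, adjusted p = 0.00507) and the tight junction gene Cldn5 from 7.08 ± 6.11 to 47.5 ± 29.2 (2.68 ± 0.46, adjusted p = 0.00735). Enpp2, which encodes autotaxin, rose from 25.4 ± 17.1 to 144 ± 106 (2.55 ± 0.47, adjusted p = 0.0148). Ttr, the thyroid hormone carrier made by choroid plexus and chosen after its values were seen, was at 218 ± 156 in mutants and 44.8 ± 48.0 in controls (3.18, adjusted p = 0.0771).

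For every gene named as changed, the 3 mutant libraries lay outside the range of the 3 controls. The naming rule asks for this of genes chosen by size of change. Of all 8622 genes, 544 lay wholly above the controls in the mutants and 584 wholly below. Limma called 15 of 8622 genes, with 636 at an unadjusted p under 0.05; edgeR called 33 (19 up, 14 down) and voom 47 (25 up, 22 down), each including all 15, and DESeq2 16, which share 13. In 1 edgeR fit of all groups, over 7531 genes, the count was 10 (8 up, 2 down), which share 7; Itm2a, Upk1b, Slco1c1, Enpp2 and Adcy8 were not among the genes tested there. The limma count was 6 without LacZ 2 or LacZ 3, 7 without control 2, 28 without control 1 and 46 without control 3. Itm2a, Ptchd1, Apoe and Upk1b kept their calls without any library. Slco1c1 and Cldn5 missed the threshold without LacZ 3 (both 0.148), Cldn5 without control 2 (0.0881), Enpp2 without LacZ 2 (0.263) or control 2 (0.0933) and in DESeq2 (0.499), and Neat1 without LacZ 2 (0.113), LacZ 3 (0.191) or control 2 (0.0972). Without LacZ 1, 2 or 3 the adjusted p was 0.0561, 0.222 and 0.13 for Ly9, 0.0713, 0.191 and 0.148 for C3ar1, 0.122, 0.0584 and 0.148 for Slc2a5, and 0.101, 0.0584 and 0.148 for Gal3st4; without control 2 it was 0.0613 for C3ar1, 0.31 for Slc2a5 and 0.127 for Gal3st4. Myo5a stood without control 1 alone, and Adcy8 and Vapa without control 3 alone (0.0507 to 0.354 for the omissions that ended these 3 calls). In 1 edgeR fit of all groups, Cldn5 (0.364), Vapa (0.214) and Gal3st4 (0.071) did not pass, in DESeq2 Adcy8 did not (0.163), and under quantile normalization Vapa did not (0.0557).

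In the Il34 forebrain the homeostatic list was shifted down and lists of activation genes were shifted up, with few members called over all genes. The homeostatic list was lower in 25 of 29 members, with a median of -0.20 (camera adjusted p = 0.000505; 0.521 with an estimated correlation). Slc2a5 fell over all genes, and 9 members fell adjusted over the list alone, among them the crystallin Crybb1 (-0.97), P2ry12 (-0.47) and the microglial membrane protein gene Tmem119 (-0.35). The disease-associated list was higher in 18 of 23 members (median 0.31, adjusted p = 1.05e-05; 0.492 with an estimated correlation). Apoe rose over all genes and 10 members rose adjusted over the list alone, including Clec7a (1.31) and Lpl (1.15), whose adjusted p over all genes was 0.0771 for both. Inflammatory cytokines and NF-kB targets were higher in 14 of 17 members (median 0.36, adjusted p = 0.000505; 0.492 with an estimated correlation). Limma called 0 over all genes, while adjusted over the list alone 4 rose: the chemokines Ccl3 (272 ± 153 against 96.9 ± 26.4), Ccl4 and Ccl12, and Nfkbiz.

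Smaller upward shifts were called for lipid efflux genes (9 of 13 positive, median 0.14, adjusted p = 0.0315; Apoe up over all genes; Apoe, Lpl and the transfer protein Pltp up adjusted over the list alone) and immediate early genes (11 of 17, median 0.30, adjusted p = 0.0315; 0 over all genes by limma; Fos, Egr1 and Junb up adjusted over the list alone). Antigen presentation genes (11 of 15, median 0.12, adjusted p = 0.0357) had 0 members over all genes and H2-K1 (0.75) up adjusted over the list alone. Interferon-stimulated genes (15 of 20, median 0.22, adjusted p = 0.0218) and ribosomal protein genes (51 of 69, median 0.12, adjusted p = 0.0218) had 0 members on either scale. With an estimated correlation the adjusted p was 0.743 for immediate early genes, 0.499 for ribosomal protein genes and 0.492 for the other 3 lists. The homeostatic, disease-associated and inflammatory calls stood without any library. The interferon call was lost without LacZ 3 (0.128) or control 2 (0.115), and that of ribosomal protein genes without LacZ 1 (0.183), LacZ 3 (0.0577), control 1 (0.138) or control 2 (0.0984). Without LacZ 2, LacZ 3, control 1 and control 2 the adjusted p was 0.123, 0.159, 0.138 and 0.115 for antigen presentation and 0.0557, 0.11, 0.163 and 0.0984 for lipid efflux; for immediate early genes it was 0.361 without LacZ 3, 0.15 without control 1 and 0.434 without control 2. Complement genes were not called as a list (adjusted p = 0.738): C3ar1 rose over all genes, and adjusted over the list alone C3ar1, Itgax and C5ar1 rose while C1qc (-0.90) and Itgam fell. The lists whose median, mean and test differed in sign were lysosome (-0.00, 0.06, up), complement (-0.05, 0.10, up) and glycolysis (-0.01, -0.02, up), none called. The endothelial list, with 3 members measured and Cldn5 up over all genes, was not called either (median 0.14, mean 0.98, adjusted p = 0.0694).

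**Figure D2:**
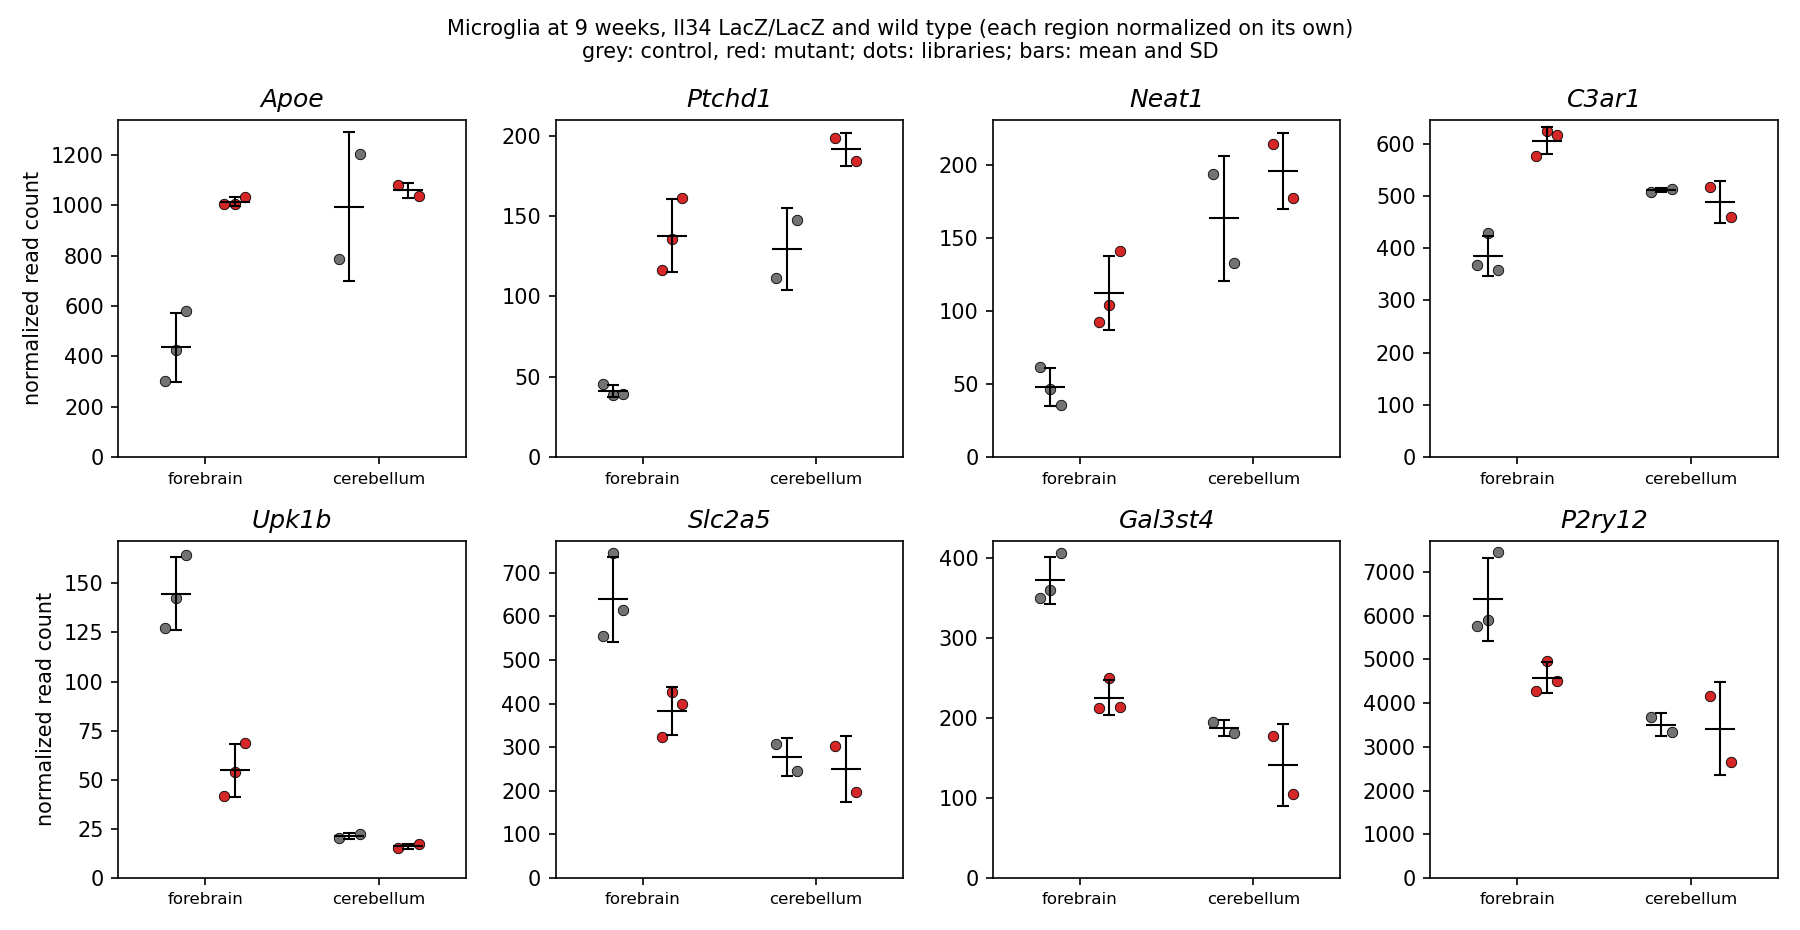
Normalised read counts (deposited values, vertical axis, 1 panel per gene) of 8 genes in microglia of Il34 wild-type controls (grey) and LacZ mutants (red) from forebrain (3 and 3 libraries) and cerebellum (2 and 2) at 9 weeks. Dots are libraries and bars are mean ± SD. The regions come from separate tables, each treated as normalized on its own. In forebrain the mutant libraries lie above the controls for Apoe, Ptchd1, Neat1 and C3ar1 and below them for Upk1b, Slc2a5 and Gal3st4; P2ry12 did not pass over all genes.

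In the cerebellum of Il34 mutants, with 2 libraries per group, 2 genes passed and both rose. Ttr (chromosome 18, 20665280 to 20674321) rose from 3.57 ± 1.36 to 349.6 ± 61.3 (SD, n = 2 each; log2 change 6.28 ± 0.41, adjusted p = 9.44e-05). Cd209a, a C-type lectin of dendritic cells (chromosome 8, 3743397 to 3748984), rose from 1.49 ± 0.397 to 96.1 ± 30.6 (5.26 ± 0.58, adjusted p = 0.0103). Antigen presentation genes Cd74 (573 ± 69.9 against 167 ± 131, 2.04, adjusted p = 0.997) and H2-Ab1 (1.59) did not pass. Monocyte markers were the 1 list called, with 4 of 4 positive and a median of 1.52 (camera adjusted p = 0.00488; 0.922 with an estimated correlation). Its members Ccr2, the chemokine receptor of inflammatory monocytes (2.21), and Chil3 (2.60) rose adjusted over the list alone and not over all genes, beside Fn1 (0.84) and Gsr (0.80). Homeostatic and disease-associated genes were not called (adjusted p = 0.773 and 0.210), and Apoe had a log2 change of 0.12. The glycolysis list (median 0.03, mean -0.04, test down) and the endothelial list (-0.19, 0.20, up) differed in sign without a call.

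Limma called 2 of 9466 genes here, with 216 at an unadjusted p under 0.05; edgeR and voom called 2 and DESeq2 3, and 1 edgeR fit of all groups, in which Ttr and Cd209a were not among the genes tested, called 0. With single libraries left out the count was 5 without LacZ 1 (2 up, 3 down), 344 without LacZ 2 (38 up, 306 down) and 5 without control 2, so most calls without LacZ 2 are lower in the mutants, while Ttr and Cd209a kept their calls without any library; in these fits the lone library is assumed to vary like the other group. The 2 LacZ libraries differed most among the 35 pairs within groups (chi-square per degree of freedom 6.87), with 48 and 3 genes at zero. The monocyte call was lost without LacZ 2 (adjusted p = 0.151) or control 1 (0.369). Only 8% of simulated 2-fold changes were recovered with 2 libraries per group, so most such changes would be missed in this comparison.

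Whether effects differed between regions, mutants or ages was asked of 7 pairs of comparisons, as the difference of the log2 changes with its combined SE and by a joint limma test chosen after seeing the data. The clearest age difference lay in the Csf1 cerebellum, where 3 of 8205 shared genes passed (704 at an unadjusted p under 0.05). Jam2 changed by -1.76 at P8 and 0.09 at 9 weeks, a difference of 1.85 ± 0.30 (joint adjusted p = 0.00597), and Cd9 by -0.95 and 0.23, a difference of 1.18 ± 0.18 (joint adjusted p = 0.00971). Ier2 went from 1.89 to -0.31, a difference of -2.21 ± 0.36 (joint adjusted p = 0.0133). The corresponding values for Spp1 (3.82 ± 1.00, joint adjusted p = 0.249) and Apoe (1.11 ± 0.24, 0.0889) did not pass. EdgeR called 16 genes and DESeq2 31 in this contrast. Limma called 52 genes without control 2, 6 without control 1 and 1 without NesCre 4 of the 9-week cerebellum, and 15 without NesCre 1, 1 without NesCre 2, 5 without control 1 and 18 without control 3 of the P8 cerebellum. Jam2 kept its call without any library and lost it with a block on replicate number (adjusted p = 0.054). Cd9 lost its call with that block (0.109), without NesCre 4 at 9 weeks (0.0754) or NesCre 2 at P8 (0.0655), and Ier2 without NesCre 1 (0.075), NesCre 4 (0.0851) or control 3 (0.129) at 9 weeks, or NesCre 2 (0.0655) or NesCre 3 (0.0786) at P8.

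Between the mutants, 1 of 8227 genes differed in the 9-week forebrain (561 at an unadjusted p under 0.05): Itm2a changed by -0.70 in Csf1 mutants and 3.66 in Il34 mutants, a difference of -4.36 ± 0.61 (joint adjusted p = 0.00141). Apoe (-0.98 ± 0.21) and Upk1b (1.07 ± 0.27) had a joint adjusted p of 0.276 each. EdgeR called 1 gene and DESeq2 5, and limma 9 without control 3 and 3 without LacZ 1 of the Il34 forebrain, and 3, 2 and 4 without NesCre 1, NesCre 3 and control 1 of the Csf1 forebrain. In the other 5 contrasts the joint limma test and edgeR and DESeq2 called 0 genes. For cerebellum against forebrain, 359 genes had an unadjusted p under 0.05 in the Csf1 mutants at 9 weeks, 377 at P8 and 419 in the Il34 mutants. The number was 465 for Csf1 against Il34 mutants in cerebellum and 426 for the 2 ages in the Csf1 forebrain. The effect at P8 on Spp1 in cerebellum exceeded that in forebrain by -3.17 ± 0.75 on the log2 scale and that on Jam2 by -1.55 ± 0.40, with a joint adjusted p of 0.998 for both; the regional difference is therefore not shown by this test. Apoe differed by -1.15 ± 0.37 between cerebellum and forebrain of Il34 mutants (0.897). Without LacZ replicate 2 of the cerebellum the Il34 contrast called 62 genes, and the P8 contrast called 1 without NesCre 3 of the forebrain. The cerebellar contrast of the mutants called 1 without NesCre 3 and 2 without LacZ 1, and that of the 2 ages in forebrain 1 without control 3 of 9 weeks.

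**Figure D3:**
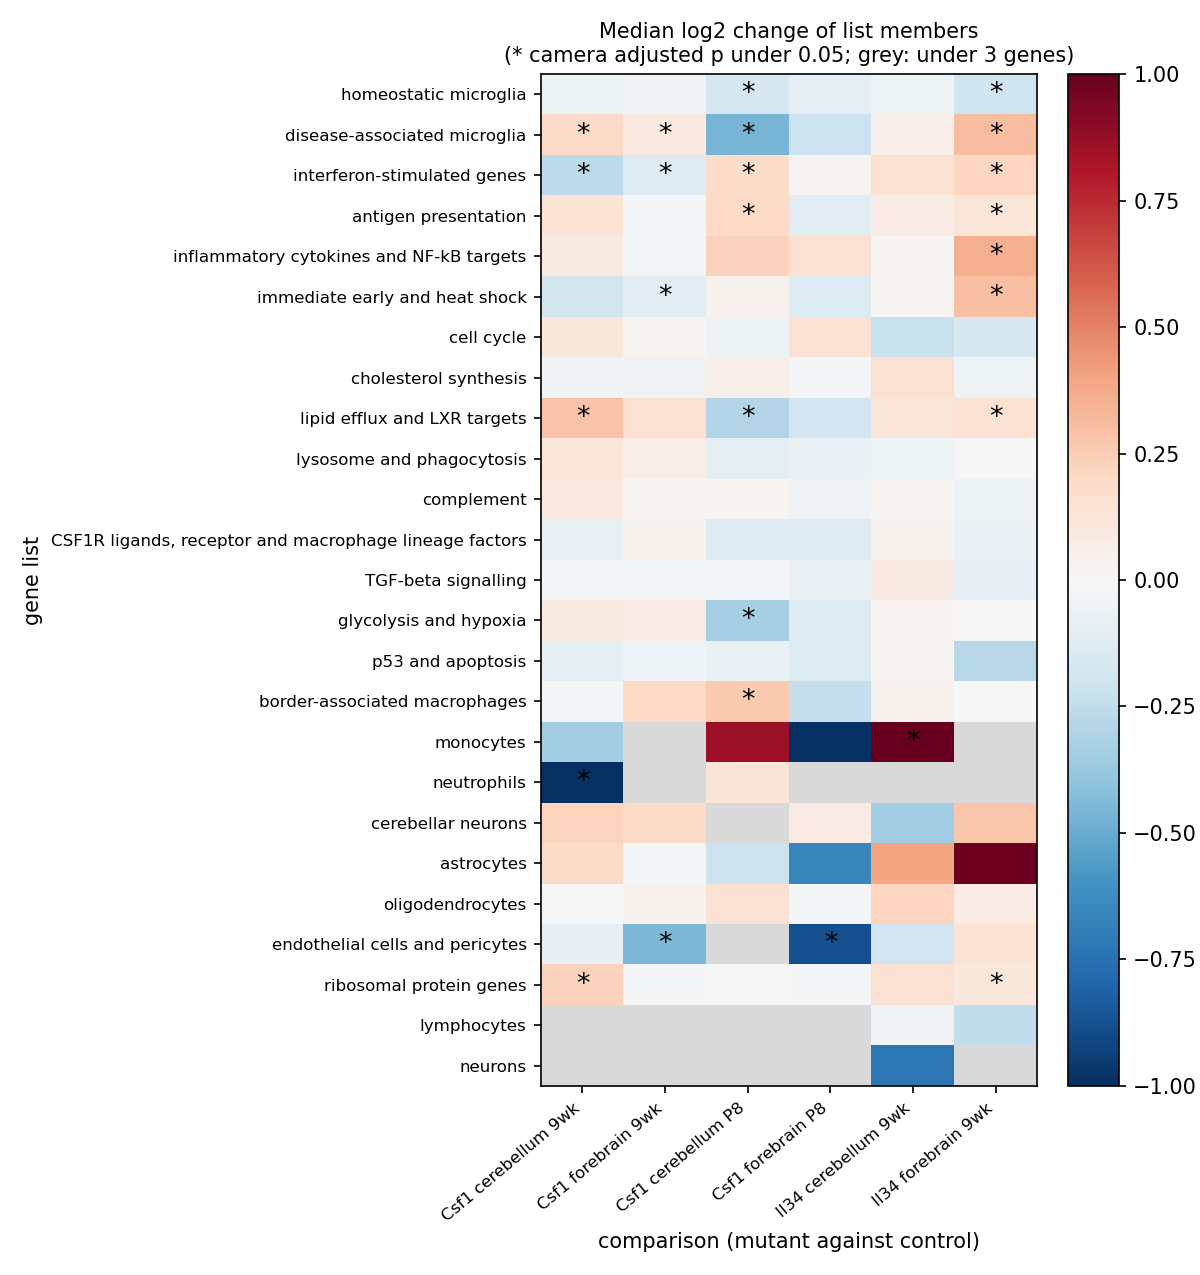
Median log2 change (colour, mutant against control) of the measured members of each gene list (vertical axis) in the 6 genotype comparisons (horizontal axis); a star marks a camera adjusted p under 0.05 at the preset correlation, and grey marks lists with fewer than 3 measured members. Disease-associated genes are negative in the P8 cerebellum (-0.47) and positive in the Il34 forebrain (0.31), and no starred list passes with an estimated correlation.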

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

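The test of shared variation between libraries was chosen after its result was seen, and the joint test of the differences between effects and the GC correction after seeing the data.

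Effects that differed between groups were seen for 4 genes. In the cerebellum of Csf1 mutants, the effects at 9 weeks and at P8 differed for Jam2 (1.85), Cd9 (1.18) and Ier2 (-2.21), and in the 9-week forebrain the effect on Itm2a differed between Csf1 and Il34 mutants (-4.36). For the contrast of ages, 10 of 100 splits gave at least the real count of 3 genes (highest other 76), and for the contrast of mutants 27 of 100 gave at least 1 (highest other 68). Chance is not excluded for either count, and splits that call many times the real count point to a structure of the samples. In the single group of 4 libraries, 0 of 8 tested values had a sample far from the others.

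For the counts of each comparison, 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real count was 34 in the P8 cerebellum, reached by 1 of the 10 splits (highest other 0). It was 15 in the Il34 forebrain, reached by 2 of 10; the highest other, 31, puts LacZ 1 with controls 1 and 2. In the 9-week cerebellum and the P8 forebrain the real count of 0 is met by 10 of 10, with highest others of 11 and 7. Any split reaches a count of 0, so for these and the other real counts of 0 below the share of splits says nothing about chance. In the 9-week forebrain all 35 of 35 splits gave at least the real 0. The split that joins controls 2 and 3 with NesCre 2 and 4 called 120 genes. The split that joins controls 1 and 3 with NesCre 1 and 3, and so parts odd from even replicate numbers, called 108. These splits point to a structure of the samples other than genotype. The contrasts of regions in Csf1 mutants at 9 weeks and at P8, and of ages in forebrain, gave 0 genes, met by 100 of 100 splits each, with highest others of 138, 58 and 27.

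The P8 cerebellum pattern, C1qc, Spi1, Lamp1 and 27 further genes higher and Spp1, Jam2, Cd9 and Ctsd lower, was weighed against 3 technical explanations. The 30 higher genes had a median GC content of 55.3% and the 4 lower ones 45.8%, against 48.8% over all genes. After a per-library GC correction 26 of the 30 higher genes and 4 of the 4 lower ones still passed (medians 1.33 and -1.32). The change therefore does not rest on the average GC trend of each library alone. The correction removes only that trend, and the genes were chosen in these same data, so it does not decide on GC content. Without the shallow mutant replicate 3 the medians were 1.34 and -1.43 (1.38 and -1.35 with it). The genes were called with that library in the fit, which favours genes on which all mutant libraries agree. The medians therefore show only that the change does not rest on that library alone, and they do not decide on its depth. Without it limma called 12 genes, 10 of them among the 34. Variation between libraries shared by the 30 genes stays open. In 4 of 5 other tables (29 or 30 of them measured) they correlate within groups beyond the 99th percentile of random sets. Those sets were matched on expression level and not on GC content. The score of these genes ranges by up to 1.06 within a group of another table, and the difference between genotypes here is 1.53. In the 9-week Csf1 groups of both regions, libraries numbered 1 or 3 scored above their group mean and those numbered 2 or 4 below it. These tables may hold the same animals and may not be separate evidence. Within the groups of the P8 cerebellum itself the score ranges by at most 0.392 (mean pairwise correlation 0.178, above the 99th percentile of 0.119), which does not rule out a state shared by the libraries of 1 genotype. The 30 genes were called in this table, which favours a large difference between genotypes and a small range within groups. The 1.53 and the 0.392 therefore cannot be weighed against the 1.06 of another table. For the lower genes the correlation with that score was 0.0705, 0.17 and 0.654 in the 3 other tables that hold all 4, and -0.283 and -0.446 in the 2 that hold 3 of them (median 0.0705), so whether they belong to the same variation cannot be told apart. In the P8 forebrain the score was 0.618 higher in mutants, with overlapping libraries (0.311 to 0.970 in mutants, -0.417 to 0.455 in controls). That table may hold the same animals. The difference was -0.0608 and 0.197 in the Csf1 cerebellum and forebrain at 9 weeks. In the Il34 cerebellum and forebrain it was 0.173 and -0.311. A genotype effect on the 30 genes and a library state that happened to follow genotype in 3 against 3 libraries may both fit these values.

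The second pattern is that some transcripts known from endothelium or choroid plexus were higher in Il34 mutants: Itm2a, Slco1c1, Cldn5 and Enpp2 passed in forebrain and Ttr in cerebellum. Of a list of 20 abundant endothelial transcripts 9 were measured in forebrain, with a median log2 change of 0.169. The bound set before that value was seen, a median under 0.5 with 8 or more measured, was met and would count against endothelial RNA; the reading was changed to undecided after the value was seen, because Ly6e, Cd34 and Bsg have control levels of 593, 264 and 202 against a table median of 40 and cannot show a small share. The 6 members below that median had a median change of 2.16, from Itm2a (3.66), Slco1c1 (3.00), Cldn5 (2.68) and Ptprb (1.64) to Kdr (0.14) and Pecam1 (0.13). In Csf1 mutants at P8 the list was higher in 1 of 11 measured members in forebrain (median -0.43, Itm2a -2.35, Cldn5 -1.97) and 2 of 6 in cerebellum (-0.27, Cldn5 -3.29). At 9 weeks it was higher in 6 of 16 in forebrain (-0.07) and 11 of 17 in cerebellum (0.30), where Ttr changed by -1.58. Large values for such transcripts therefore also stand in Csf1 mutants at P8, but they are negative and did not pass over all genes. They do not show whether the rise is particular to the Il34 mutants. In the 9-week forebrain Itm2a changed by -0.70 in Csf1 mutants and 3.66 in Il34 mutants (joint limma adjusted p = 0.00141). It was the only gene called in that contrast, and chance is not excluded for that count. In the cerebellum 3 of 14 choroid plexus transcripts were measured, with a median of 3.29 (Ttr 6.28, Enpp2 3.29, Prlr -0.24), too few to decide; RNA from such cells, which the sort should remove, and a change in microglia cannot be told apart, and no biological explanation was tested.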

How the results depend on the processing

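Tests with edgeR, DESeq2 and voom of the genotype effects, the GC correction, the fit of all groups, the variance trend, and list tests under the block or without single libraries were chosen after seeing the data. For the 123 calls that the naming rule selects (gene and comparison counted as a pair), a part of all calls (19 of the 34 in the P8 cerebellum), 1423 alternative values were computed: 1122 stayed past the threshold, 301 did not and 0 reversed. Quantile normalization, the stricter filter and the pseudocount of 0.1 left the 6 genotype counts within 1.5 times the main count. The stricter filter removed no gene from any table but that of the P8 forebrain, where 9580 of 9612 stayed. It was therefore almost the main fit again and tests little. For each changed count below the cause was not tested, except where it is given.

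DESeq2 called 1 gene in the Csf1 cerebellum and 2 in the forebrain at 9 weeks, where limma called 0. In the P8 cerebellum (limma 34) edgeR called 52, DESeq2 69 and voom 69. In the Il34 forebrain (limma 15) edgeR called 33 with TMM and 33 with RLE factors, and voom 47. The fit of all groups called 0 in the Il34 cerebellum (limma 2), where the 2 genes are not among those tested. For differences between effects, DESeq2 called 5 for the mutants in forebrain (limma 1), and edgeR 16 and DESeq2 31 for the ages in cerebellum (limma 3). For regions at P8 DESeq2 called 20 (edgeR 12).

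Same-numbered libraries did not deviate together in a way that shows pairing: in no set of 3 or more pairs was every correlation over 0.1. At 9 weeks each numbered cerebellum library of the Csf1 controls and of the mutants did match its own number best in forebrain, with correlations of 0.0562 to 0.298 and 0.0768 to 0.133, so the numbers may mark animals there. With a block on replicate number the counts were 35 and 12 in the Csf1 cerebellum and forebrain at 9 weeks, 8 in the P8 forebrain, 10 in the Il34 cerebellum and 79 in the Il34 forebrain (43 up, 36 down). The fits of the 9-week cerebellum, the P8 forebrain and the Il34 cerebellum held only 2 shared numbers. They leave very few residual degrees of freedom, so their counts say little about genotype. With the block in the P8 cerebellum 47 passed (34 up, 13 down). For differences between effects the block gave 2 (regions, Csf1 9 weeks), 4 (regions, P8), 4 (mutants in forebrain) and 1 (ages in cerebellum), and for regions in controls 362 at 9 weeks, 41 at P8 and 19 in the Il34 set (17 higher, 2 lower). Lists called under the block were 0 in the 9-week forebrain and 2 in the P8 forebrain.

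Lists called fell from 5, 4, 7, 1, 1 and 8 (Csf1 cerebellum and forebrain at 9 weeks, cerebellum and forebrain at P8, Il34 cerebellum and forebrain) to 0 in each with an estimated correlation, and to 0 in each with fry's directional test. For regions they fell from 6, 9 and 8 (Csf1 9 weeks, P8, Il34) to 3, 0 and 0 with an estimated correlation, and to 0 at P8 and 1 in the Il34 set with fry. With no filter the regions gave 71, 12 and 48 genes (71, 12 and 49 with it). A variance trend gave 8 in the 9-week cerebellum and 5 in the P8 forebrain, and the GC correction 2 in the 9-week forebrain and 2 in the P8 forebrain. Keeping only members above the expression minimum left every list count as it was.

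With each library left out in turn, genes called ranged from 0 to 3 in the Csf1 cerebellum and 0 to 1 in the forebrain at 9 weeks, 6 to 60 in the P8 cerebellum, 0 to 1 in the P8 forebrain, 2 to 344 in the Il34 cerebellum and 6 to 46 in the Il34 forebrain; the high ends are without control 2; NesCre 1, control 2 or control 3; control 3; NesCre 3; LacZ 2; and control 3. For differences between effects the ranges were 0 to 0 (regions, Csf1 9 weeks), 0 to 1 (regions, P8), 0 to 62 (regions, Il34), 0 to 2 (mutants in cerebellum), 1 to 9 (mutants in forebrain), 1 to 52 (ages in cerebellum) and 0 to 1 (ages in forebrain). For regions in controls they were 28 to 74, 3 to 40 and 6 to 65 (Csf1 9 weeks, P8, Il34). Lists called ranged from 4 to 5, 0 to 5, 2 to 8, 1 to 6, 0 to 2 and 3 to 9 for genotype in the order above, and 4 to 9, 6 to 10 and 6 to 8 for regions.

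In simulated counts at the tables' depths the joint test of differences between effects recovered 39% of 2-fold differences for Csf1 regions at 9 weeks, 14% at P8 and 6% for Il34 regions. False calls numbered 10, 2 and 10, in the same order. For the mutants in cerebellum and in forebrain it recovered 13% and 29%, with 8 and 15 false calls. For the ages in cerebellum and in forebrain it recovered 23% and 16%, with 4 and 3 false calls.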

Other observations

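The region test, and the test of the Il34 effect along the region profile, were chosen after the data or the result were seen. The region test held only genes present in the deposited tables of both regions. Genes kept in the table of 1 region alone could not be tested. In 9-week Csf1 controls, cerebellar microglia carried less of the homeostatic program than forebrain microglia. Upk1b was at 16.8 ± 3.45 CPM in cerebellum and 134 ± 14.6 in forebrain (SD, n = 3 each; log2 difference -2.97, edgeR adjusted p = 4.43e-06), Slc2a5 lower by a log2 difference of -1.32 (1.92e-05) and P2ry12 of -0.92. The receptor kinase Axl was higher (93.3 ± 25.1 against 16.9 ± 6.24, 2.45, adjusted p = 0.000321), as were Clec7a (2.19) and Apoe (1.21). EdgeR called 71 of 9150 genes, 35 higher and 36 lower in cerebellum, and 28 without cerebellar control 3, without which Apoe missed the threshold (0.0561). Of 29 homeostatic genes 26 were lower (median -0.37, camera adjusted p = 2.89e-12; 0.0344 with an estimated correlation), 7 of them called over all genes and 20 adjusted over the list alone. Immediate early genes (20 of 22 higher, adjusted p = 4.37e-09) and inflammatory genes (15 of 19, 1.66e-06) were higher, each with 0.0344 with an estimated correlation; interferon genes were higher in 23 of 23 (4.41e-12; 0.0642 with an estimated correlation). Disease-associated (0.0176) and endothelial (0.00242) lists were higher too, both 0.456 with an estimated correlation; the first lost its call without cerebellar control 3 (0.0534) or forebrain control 1 (0.149), the second without cerebellar control 3 (0.133).

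At P8, Spp1 was at 1652 ± 493 CPM in cerebellum and 125 ± 27.8 in forebrain (n = 3 each; log2 difference 3.73, edgeR adjusted p = 2.21e-11), and Igf1 (1.15), Apoe (1.03) and Ctsd (0.68) were higher in cerebellum. EdgeR called 12 of 8374 genes, 11 higher and 1 lower. Without cerebellar control 1, cerebellar control 3, the unnumbered forebrain control, forebrain control 1 or forebrain control 2 the count was 4, 40, 3, 33 and 4. Igf1 was not called without cerebellar control 1 (0.0675) or the unnumbered control (0.0904), nor Apoe without the unnumbered control (0.089) or forebrain control 2 (0.173) or in DESeq2 (0.22). Disease-associated genes were higher in 25 of 27 (median 0.60, camera adjusted p = 6.12e-15) and lipid efflux genes in 13 of 15 (2.14e-08), cell cycle genes lower in 31 of 31 (2.75e-10); each had 0.224 with an estimated correlation. Ribosomal protein genes were lower in 72 of 73 (1.63e-13; 0.376 with an estimated correlation). Lysosome (2.89e-05), glycolysis (0.0007), complement (0.0206), interferon (0.0206) and antigen presentation (0.0241) lists were higher, and 0.298, 0.298, 0.298, 0.224 and 0.522 with an estimated correlation. The interferon call was lost without cerebellar control 2 (0.107), the unnumbered control (0.0876) or forebrain control 2 (0.113), the complement call without cerebellar control 2 (0.0525), the unnumbered control (0.0991) or forebrain control 2 (0.109), and the antigen presentation call without cerebellar control 1 (0.0518), cerebellar control 3 (0.398) or forebrain control 2 (0.467).

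In the Il34 controls, 2 cerebellum against 3 forebrain libraries, Upk1b was again lower in cerebellum (log2 difference -2.75, edgeR adjusted p = 5.7e-06) and Axl higher (2.24). EdgeR called 49 of 8358 genes, 30 higher and 19 lower; the count was 16 without cerebellar control 1, 6 without cerebellar control 2 and 7 without forebrain control 2, and Axl was not called without cerebellar control 2 (0.2) or forebrain control 2 (0.0518). With a block on replicate number edgeR called 19 genes, 2 of them lower in cerebellum. Homeostatic genes were lower in 27 of 29 (camera adjusted p = 3.13e-09), and interferon (5.9e-09), inflammatory (0.000103), ribosomal protein (0.000497), disease-associated (0.00556), antigen presentation (0.0117), immediate early (0.0153) and cerebellar neuron (0.0240) lists higher. With an estimated correlation the interferon list had 0.138, immediate early genes 0.779 and the other 6 lists 0.492. The antigen presentation call was lost without forebrain control 1 (0.0627), the immediate early call without cerebellar control 2 (0.231), forebrain control 1 (0.115) or forebrain control 2 (0.396), the neuron call without cerebellar control 2 (0.33) and the ribosomal protein call without cerebellar control 1 (0.15). For the Csf1 controls, 3 against 3 libraries make too few splits for a share under 0.05: at 9 weeks the real count of 71 was reached by 1 of 10 (highest other 1) and at P8 that of 12 by 2 of 10 (highest other 13).

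Upk1b, Slc2a5, Apoe and Ptchd1, called in the Il34 forebrain, also separate the regions in the 9-week Csf1 controls, while Cldn5 and C3ar1 did not pass there (edgeR adjusted p = 0.693 and 0.196); a move of mutant forebrain microglia towards the cerebellar profile is a hypothesis. With the profile taken from the separate Csf1 controls, 33 of 34 genes higher in cerebellum rose in value (median 1.00, camera p = 0.00222 with an estimated correlation) and 32 of 36 lower ones fell in value (median -0.43, p = 0.0673), and since the larger p misses 0.05 the test does not decide. In the Il34 cerebellum the same genes moved the same way (28 of 35 higher, median 0.33; 31 of 36 lower, median -0.17; camera p = 0.0795 and 0.391 with an estimated correlation), so the shift is not shown to be particular to forebrain. With other genes, the profile of the Il34 controls, the Csf1 mutant forebrain gave 15 of 28 and 13 of 19 (larger camera p = 0.745 with an estimated correlation), and the difference between the mutants was not tested as a profile. Cerebellar microglia mixed into the mutant forebrain libraries would need 1 share for all 70 genes. The best share of 55.2% left a heterogeneity p of 2.7e-07. The 70 genes were chosen by their region difference in the separate Csf1 controls, whose profile may differ from that of the Il34 mice. Region changes came from edgeR and mutant changes from limma on log2(value + 1), which understates low genes. Either could give heterogeneity under mixing too, so the test does not decide on mixing.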
